A study of Mus musculus with 29 samples.

How the data were processed

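Gene expression was studied by RNA sequencing in 29 mouse libraries, all labelled with the strain C57BL/6J-OG2. The labels list 20 libraries of fibroblasts under OSKM reprogramming (FLAG control, Jmjd3 overexpression, shLuc, shJmjd3 and shUtx, 2 libraries each at day 4 and day 8), 8 libraries of embryonic fibroblasts (wild type, Jmjd3 knockout, FLAG and Jmjd3 overexpression, 1 library each at passage 2 and passage 4) and 1 library of induced pluripotent stem cells at passage 13. Factors and hairpins were carried by retroviral vectors in most labels, cells were kept with vitamin C, and RNA was extracted with TRIzol, per the labels' protocols. The iPSC source is labelled as induced without c-Myc, so it differs from the other cells in its factors.

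Reads were aligned with Bowtie2 2.2.5 and quantified with RSEM 1.2.22 on mm10, per the submitters' processing notes. The method of normalization, the annotation release and the strand setting are not given in the sources used here. The deposited values are scores that the authors normalised between libraries and rounded to whole numbers. Their deposited main table holds 16077 genes. Column totals were 12358600 to 12368000 and medians 242 to 243, every column had the same maximum of 59744, and 10 genes stood at it in each library. Values therefore come in shared steps and carry no information on depth, and 4.41% to 6.07% of genes had the same value in both replicates of a group. Genes listed at 0 numbered 551 to 1213 per library. A value of 0 can be a failed estimate as well as an absent transcript. A second deposited table holds the 8 MEF libraries normalised apart, with 10707 genes, and another holds the authors' means of the 10 OSKM groups, with 11886 genes. Values were compared only within a table. The main table also holds 3 columns that match no sample of the labels, and these were not used.

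The design written before the data were examined had 20 OSKM libraries with values per library. The main table holds 16 of them, without those of shUtx, so the fit had 8 groups and 8 residual degrees of freedom. The design also allowed for values that could be tags, TPM or counts, and the scores were treated as normalised tags. Comparisons with shUtx were reduced to log2 ratios of the authors' means plus 1, without spread or p, among genes present in the table of means. The median of each list in these ratios was placed among 10000 random lists of the same size matched on mean value.

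Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with lmFit and eBayes with a trend on mean value. Genes with a mean of at least 10 over the libraries fitted were kept, 14715 in the OSKM fit and 14449 in the MEF fit. The OSKM fit had 1 coefficient per group. The comparisons were overexpression against FLAG and shJmjd3 against shLuc at each day, day 8 against day 4 over both controls, and the difference of each effect between days. The MEF fit had the kind of MEF and the passage as additive terms, with 3 residual degrees of freedom, so its spread includes any difference of an effect between passages. Its comparisons were knockout against wild type, overexpression against FLAG, FLAG against wild type, and passage 4 against passage 2. The iPSC library entered no test. The moderated p-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05. The prior degrees of freedom were 2.59 in the OSKM fit and 2.30 in the MEF fit. Equal replicate numbers of different groups share only a number, so no block was used.

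Gene lists were written before the data were examined and tested with limma's camera at a fixed correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. The lists were pluripotency, reprogramming factors, epithelial, stratified epithelium, mesenchymal, cell cycle, Ink4 and p53 targets, secretory phenotype and inflammation, H3K27 methylation machinery, cohesin with elongation and Phf20, Hox clusters, bivalent developmental regulators, interferon response, glycolysis, trophoblast, extraembryonic endoderm, endothelial, skeletal and cardiac muscle, neural and glial, macrophage, dissociation and stress, and mitochondrial transcripts. Lists with fewer than 5 measured members were counted without a set test, and no mitochondrial transcript is in the table. Members were counted with p adjusted over all genes and over the list alone. Sharing of calls between comparisons was set against the number for independent lists with Fisher's exact test, and the ratios of the 2 hairpins, which share shLuc, against simulated unchanged groups.

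The genes named follow a rule of the design. It takes Kdm6b, Kdm6a and Uty, and up to 8 genes higher and 8 lower with the largest change among those called whose libraries do not overlap between the groups. For MEFs these must change the same way at both passages, and for the passage effect in all 4 kinds. Genes named Gm or Rik, pseudogenes and unnamed genes are left out. It adds the 4 members with the smallest p of each list that passes its test or has at least 3 members called, and Cdkn2a, Cdkn2b, Cdh1, Epcam, Nanog, Phf20, Nipbl, Pou5f1 and Klf4. Where fewer than 5 genes pass, the 5 with the smallest p are given as values. Of the genes the rule takes, 2 are not reported here. A gene named under 1 comparison may also be shown in another. Positions come from GENCODE M21 on mm10, the build of the submitters' processing notes, where 16061 of the 16077 genes were matched. Symbols are those of the deposited tables.

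Each fit was tested on simulated data built from its own means and spread, with 200 genes changed. Of 2-fold and 4-fold changes, 75% and 86% were recovered for overexpression at day 8, 73% and 87% for knockdown at day 8, 47% and 64% for overexpression in MEFs, and 55% and 78% for passage, and 4.76% to 5.67% of calls were false. Correlations of log2 values were 0.929 to 0.950 between replicates, 0.908 to 0.939 between groups of a day and 0.835 to 0.892 across days.

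Alternatives planned with the design were a pseudocount of 10, no filter, a mean of at least 50, quantile normalization, a shift to equal medians, robust fitting, a replicate block, fits of 1 day or of the groups compared alone, leaving out each library in turn, no passage term, 1 fit over all 24 OSKM and MEF libraries, and the separate MEF table. Chosen after the data were seen were FLAG as the control of the knockdown, leaving out tied genes or genes at 0, other settings for the sharing of calls, and each passage alone. Figures were drawn with matplotlib 3.10.9, and tables handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.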

Results

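Gene expression was measured by RNA sequencing in mouse cells that carried extra or reduced amounts of the histone demethylase Jmjd3, which removes methyl groups from lysine 27 of histone H3 and is encoded by Kdm6b. The 29 libraries covered 3 kinds of cells. Mouse embryonic fibroblasts (MEFs) gave 8 libraries, 1 at passage 2 and 1 at passage 4 for wild-type cells, Jmjd3 knockout cells, cells infected with a FLAG control vector and cells overexpressing Jmjd3. Fibroblasts undergoing reprogramming after infection with the factors Oct4, Sox2, Klf4 and c-Myc (OSKM) gave 20 libraries, 2 for each of 5 conditions at day 4 and at day 8. These conditions were a FLAG control, Jmjd3 overexpression, a control hairpin against luciferase (shLuc), a hairpin against Jmjd3 (shJmjd3) and a hairpin against Utx (shUtx), the related demethylase encoded by Kdm6a. A line of induced pluripotent stem cells (iPSCs) at passage 13 gave 1 library. Values were the authors' normalised expression scores for 16077 genes, with nearly equal totals of 12358600 to 12368000 per library, so the sequencing depth behind them is unknown. The 4 shUtx libraries entered only as the authors' group means. In OSKM cells the values of Pou5f1 (Oct4), Sox2, Klf4 and Myc may include transcripts of the vectors, which the scores do not separate. Values below are means ± SD of 2 libraries or the values of each library. Nothing in the labels places replicates in separate cultures, so p-values measure the spread between these libraries, which may be technical. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values.

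The targeted gene was examined first. Kdm6b lies on chromosome 11 from 69398508 to 69413675 in mm10. In OSKM cells it was listed at 1218 and 1168 in the FLAG libraries of day 4 and at 10671 in both overexpression libraries. At day 8 the FLAG libraries held 1514 and 1538 and both overexpression libraries 13215. The log2 change was 3.16 at day 4 and 3.11 at day 8, with adjusted p of 1.6e-09 and 1.8e-09 in limma with Benjamini-Hochberg adjustment. Under the hairpin, Kdm6b fell from 1464 and 1498 in shLuc to 518 and 428 in shJmjd3 at day 4, and from 1346 and 1350 to 476 and 467 at day 8. The log2 changes were -1.65 and -1.51 (limma adjusted p = 5.1e-08 and 1.0e-07). Among MEFs, the overexpressing libraries held 42160 at passage 2 and 10671 at passage 4, against 676 and 579 with FLAG. Knockout MEFs held 377 and 408, against 578 and 652 in wild-type MEFs. The part of the gene deleted in these cells is not given in the sources used here, so a value over the whole gene does not check that label. The iPSC library held 811. Kdm6a, on chromosome X from 18162575 to 18279936, and its Y-linked relative Uty were not called under Jmjd3 overexpression or knockdown, with Kdm6a between -0.08 and 0.02 in log2 change over the 4 comparisons.

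**Figure D1:**
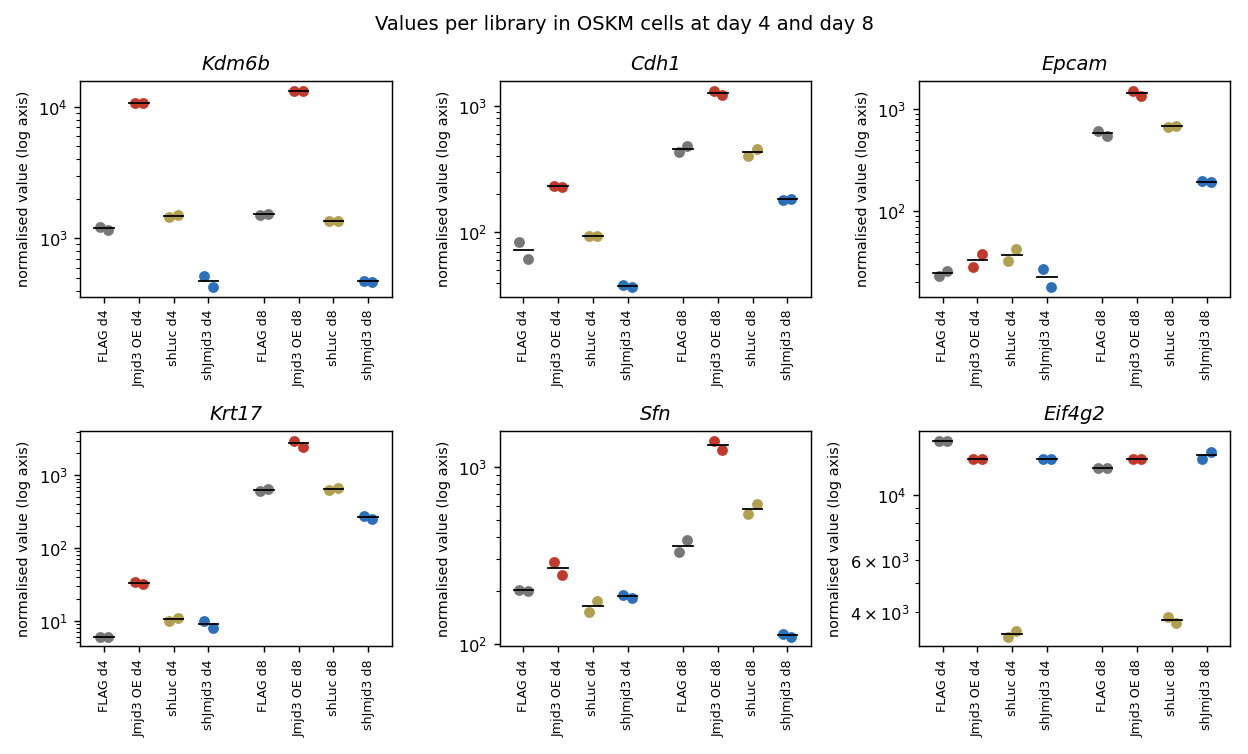
Normalised values of 6 genes in each of the 16 OSKM libraries with their own values, on a log axis, by condition and day; points are libraries and the black line is the mean of the 2 libraries of a group. Kdm6b reached 10671 and 13215 under overexpression, Cdh1, Epcam, Krt17 and Sfn were higher with overexpression and lower with shJmjd3 at day 8, and Eif4g2 was between 3288 and 3849 in the shLuc libraries.

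Jmjd3 overexpression at day 4 was compared with the FLAG control to show which genes respond early in reprogramming. Genes of epithelia rose. Cdh1, the epithelial adhesion molecule E-cadherin, went from 73 ± 15.6 (SD, n = 2) to 230.5 ± 2.12 (SD, n = 2), Krt8, a keratin of simple epithelia, from 112 ± 3.54 to 368 ± 26.2, and Krt17, a keratin of stratified epithelia, from 6 in both libraries to 33 ± 1.41. Cell cycle genes fell together, with the DNA topoisomerase Top2a going from 4978 in both libraries to 2991 ± 236 and cyclin A2 (Ccna2) from 2081 ± 43.8 to 1404 ± 33.9. Cdkn2a, which encodes the growth-arrest proteins p16Ink4a and p19Arf, rose from 465 ± 26.9 to 1118 ± 73.5, and its neighbour Cdkn2b from 419.5 ± 34.6 to 627 ± 63.6.

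Of 14715 genes tested with limma at day 4, 1900 were called at an adjusted p under 0.05, 1004 higher and 896 lower, of which 186 and 33 changed by 2-fold or more. The epithelial list had 11 of 25 members higher and 0 lower (14 and 1 adjusted over the list alone), with a camera adjusted p of 4.8e-08 and an adjusted p = 0.017 with an estimated correlation. Keratins and other genes of stratified epithelium rose in 10 of 18 cases (11 adjusted over the list alone, camera adjusted p = 5.1e-09, adjusted p = 0.017 with an estimated correlation), led by Krt17 at a log2 change of 2.28 (SE 0.13) and Krt16 at 1.84 (SE 0.18). The cell cycle list fell in 25 of 28 genes (26 adjusted over the list alone, camera adjusted p = 4.4e-23, adjusted p = 0.023 with an estimated correlation). At day 4 its median was also below the control with shJmjd3, at -0.21 against shLuc. In the shUtx means, which have no test, it was at -0.19 against shLuc and -0.21 against FLAG. A lower cell cycle list was thus not particular to overexpression. Among cohesin, transcription elongation and Phf20 genes 9 of 23 fell (13 adjusted over the list alone, camera adjusted p = 1.9e-06, adjusted p = 0.017 with an estimated correlation), among them the cohesin subunit Smc3 at -0.70 and the cohesin loader Nipbl at -0.33, while Phf20 itself was at -0.10 and not called. Hox genes fell in 5 of 28 cases (7 adjusted over the list alone, camera adjusted p = 0.0010, adjusted p = 0.023 with an estimated correlation). Mesenchymal genes rose in 7 of 30 cases (7 higher and 1 lower adjusted over the list alone), including the actin-binding protein transgelin (Tagln) at 0.59, with a camera adjusted p of 0.0089 and an adjusted p = 0.033 with an estimated correlation. The list of Ink4 and p53 targets had 5 of 21 members higher (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0030), with an adjusted p = 0.067 with an estimated correlation. In the list of H3K27 methylation machinery 6 of 21 genes fell, such as the methyltransferase Ezh2 at -0.27 and its partner Suz12 at -0.29, and the only member that rose was Kdm6b (camera adjusted p = 0.0089, adjusted p = 0.13 with an estimated correlation). Other lists passed camera at day 4 but not with an estimated correlation. Extraembryonic endoderm rose in 3 of 8 genes (camera adjusted p = 0.0095, adjusted p = 0.067 with an estimated correlation), interferon response in 2 of 22 (0.011 and 0.12), muscle in 1 of 5 (0.018 and 0.14), neural in 2 of 9 (0.024 and 0.13), trophoblast in 1 of 7 (0.032 and 0.11) and glycolysis in 2 of 18 (0.038 and 0.11), and the secretory phenotype rose in 3 and fell in 1 of 19 (0.011 and 0.14).

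Several of the largest calls at day 4 were genes listed at or near 0 in one group. The potassium channel gene Kcnj3 was listed at 0 in both FLAG libraries and 39 and 210 with overexpression. The olfactory receptor Olfr113 was listed at 158 and 210 and at 0 in both overexpression libraries. Values of such receptors are uncertain, since near-identical copies can share reads. The count of calls at day 4 was 1109 without FLAG replicate 1, 1140 without FLAG replicate 2 and 961 without overexpression replicate 1, and 332 when only the 4 libraries compared were fitted.

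At day 8 Jmjd3 overexpression raised epithelial genes again and pluripotency genes as well. Cdh1 went from 458 ± 37.5 (SD, n = 2) to 1265 ± 65.1 (SD, n = 2) and Epcam, an epithelial adhesion molecule also present on pluripotent cells, from 576 ± 41.7 to 1421 ± 119. Tdgf1, a co-receptor of pluripotent cells, rose from 82 ± 17.0 to 748 ± 124, and Tet1, which oxidises methylcytosine, from 343 ± 18.4 to 628 ± 47.4. Sfn, an adaptor protein of stratified epithelium, rose from 358 ± 38.2 to 1329 ± 113. Cdkn2a was again higher, at 1844 ± 8.49 against 1138 ± 8.49. Klf4, also carried by the reprogramming vectors, was lower, at 13992 in both overexpression libraries against 19856 in both FLAG libraries.

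limma called 2973 genes at day 8, 1459 higher and 1514 lower, with 327 and 93 of them past 2-fold. Calls were more frequent at higher transcript GC content, with 75 of 1471 genes in the lowest 10% and 412 of 1470 in the highest 10%. The cause was not tested. In the epithelial list 16 of 25 members rose and 0 fell (21 adjusted over the list alone), with a median log2 change of 1.26, a camera adjusted p of 4.0e-13 and an adjusted p = 0.0038 with an estimated correlation. The stratified epithelium list rose in 16 of 18 genes (17 adjusted over the list alone) at a median of 2.79 (camera adjusted p = 3.8e-15, adjusted p = 0.0046 with an estimated correlation), with Krt16 at 2.64 (SE 0.18) and Krt6a at 2.27 (SE 0.15). Pluripotency genes rose in 14 and fell in 2 of 24 cases (15 and 2 adjusted over the list alone, camera adjusted p = 7.7e-07, adjusted p = 0.016 with an estimated correlation), and Nanog, at 382 and 395 against 212 in both FLAG libraries, was not called (adjusted p = 0.25). Interferon response genes rose in 10 and fell in 1 of 22 cases (12 and 1 adjusted over the list alone, camera adjusted p = 3.4e-05, adjusted p = 0.032 with an estimated correlation), including the RNA sensor Ddx58 at 1.02 (SE 0.09). Over 26 members, the median value of this list was 58.75 with overexpression, 29.5 with FLAG and 60 with shLuc. Overexpressing cells were thus not above the other control, and low values with FLAG cannot be told apart from an effect of overexpression. Ink4 and p53 targets rose in 10 and fell in 3 of 21 cases (11 and 3 adjusted over the list alone, camera adjusted p = 3.4e-05, adjusted p = 0.026 with an estimated correlation), with the membrane protein Perp at 0.83 and the death receptor Fas at 0.68. By camera the Ink4 and p53 list was also higher with shLuc than with FLAG at day 8, so the same limit applies. Genes of the secretory phenotype and inflammation rose in 8 and fell in 1 of 19 cases (camera adjusted p = 0.00016, adjusted p = 0.064 with an estimated correlation), led by the adhesion receptor Icam1 at 1.93 (SE 0.17). Among markers of other lineages, 3 of 7 trophoblast genes, 3 of 5 muscle genes and 3 of 9 neural genes rose, with camera adjusted p of 0.031, 0.016 and 0.031, and an adjusted p = 0.095, 0.14 and 0.14 with an estimated correlation. Extraembryonic endoderm genes rose in 4 and fell in 1 of 8 cases (camera adjusted p = 0.053) and endothelial genes in 1 and 1 of 5 (camera adjusted p = 0.94).

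Genes that fell at day 8 included those of the Hox clusters, 9 of 28 (9 adjusted over the list alone, camera adjusted p = 5.6e-05, adjusted p = 0.013 with an estimated correlation), with Hoxb8 at -1.52 (SE 0.26) and Hoxc8 at -0.95 (SE 0.12). Glycolysis genes fell in 10 of 18 cases (10 adjusted over the list alone, camera adjusted p = 0.0041, adjusted p = 0.034 with an estimated correlation), and the 1 that rose was the glucose transporter gene Slc2a3 at 1.31 (SE 0.08). At day 8 the glycolysis list was also lower than FLAG with shLuc and with shJmjd3. High values in the FLAG libraries can therefore not be told apart from an effect of overexpression. The cell cycle list, lower at day 4, had 2 members higher and 1 lower at day 8 by limma (camera adjusted p = 0.58). Among the largest rises were Sprr3 and Sprr2a3, which encode proteins of the cornified cell envelope, at 161 and 119 against 6 and 1 and 203 and 242 against 3 and 5, with Sprr2a3 less certain because its cluster holds near-identical copies. The largest falls outside the olfactory receptors were Sost, at 62 and 88 with FLAG and 10 and 16 with overexpression, and Adamts19. The count of calls was 1769 without FLAG replicate 1, 1938 without FLAG replicate 2 and 1495 without overexpression replicate 1, and 1446 when only the 4 libraries compared were fitted.

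Knockdown of Jmjd3 was compared with the shLuc hairpin at day 4 to show what its loss changes early. Several epithelial genes fell against both controls. Cdh1 was at 37.5 ± 0.707 (SD, n = 2) with shJmjd3, 93.5 ± 0.707 (SD, n = 2) with shLuc and 73 ± 15.6 with FLAG, and Krt8 at 67 ± 11.3, 224 ± 23.3 and 112 ± 3.54. The lactate transporter gene Slc16a3 fell to 15 ± 1.41, from 80 ± 11.3 with shLuc and 79 ± 9.90 with FLAG. Some mesenchymal genes rose against shLuc, with the collagen gene Col3a1 at 59744, the highest value of the table, in both shJmjd3 libraries and 25878 ± 2805 with shLuc, and N-cadherin (Cdh2) at 3352 ± 76.4 against 1962 ± 122.

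With limma 5661 genes were called at day 4, 2771 higher and 2890 lower, 268 and 424 of them past 2-fold. Against the FLAG libraries, a control chosen after the data were seen, 3724 genes were called, and 2414 genes were called in the same direction against both controls, which share the shJmjd3 libraries. The mesenchymal list had 14 of 30 genes higher and 2 lower (15 and 3 adjusted over the list alone, camera adjusted p = 0.0077), with an adjusted p = 0.099 with an estimated correlation. Against FLAG it had 11 higher and 1 lower (camera adjusted p = 0.00035, adjusted p = 0.030 with an estimated correlation). Epithelial genes fell in 10 and rose in 2 of 25 cases (11 and 2 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.28 with an estimated correlation), with Lad1, a protein of epithelial anchoring junctions, at -1.28 against shLuc and -1.05 against FLAG. Against FLAG 5 epithelial genes fell and 2 rose (camera adjusted p = 0.26). Stratified epithelium rose in 4 and fell in 2 of 18 cases against shLuc (camera adjusted p = 0.50). Among the risers were Krt6a at 2.12 and Krt16 at 1.00, which also rose with overexpression at day 4. Cell cycle genes fell in 16 and rose in 3 of 28 cases (16 and 3 adjusted over the list alone, camera adjusted p = 0.00057, adjusted p = 0.46 with an estimated correlation), and fell in 20 and rose in 1 against FLAG (camera adjusted p = 7.5e-08, adjusted p = 0.41 with an estimated correlation). The H3K27 methylation machinery fell in 9 of 21 genes against shLuc, counting Kdm6b, the target of the hairpin, and with Suz12 at -0.60 (camera adjusted p = 0.023, adjusted p = 0.35 with an estimated correlation). Against FLAG 4 fell and 2 rose (camera adjusted p = 0.40). Interferon response genes fell in 9 of 22 cases against shLuc (camera adjusted p = 0.040, adjusted p = 0.35 with an estimated correlation), but the list went the other way against FLAG, with a camera adjusted p of 0.403. Prostaglandin synthase Ptgs2 fell by a similar amount from either control, with log2 changes of -1.30 and -1.22. Cdkn2a was lower than with shLuc, at -0.57 (SE 0.12), and at -0.12 against FLAG (limma adjusted p = 0.54), while Cdkn2b was not called. All 4 reprogramming factors were lower than with shLuc, among them Pou5f1 at -0.71, but Klf4 and Myc were at 0.01 and 0.03 against FLAG. These values do not separate transcripts of the vectors from those of the cells' own genes. Among the largest rises, the interferon-inducible gene Ifi205 was listed at 0 and 0 with shLuc, 26 and 222 with shJmjd3 and 120 and 23 with FLAG.

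A library fact bears on each comparison with shLuc. Eif4g2, which encodes a translation initiation factor, was between 3288 and 3849 in the shLuc libraries and at 12357 or above in the other 12 OSKM libraries, and was picked after its values were seen. Between the controls themselves limma called 3934 genes at day 4 and 5153 at day 8.

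At day 8 epithelial genes were lower with the knockdown than with either control. Pluripotency and interferon lists were lower as well, but each passed with an estimated correlation against 1 of the 2 controls only. Cdh1 was at 182 ± 2.12 (SD, n = 2) with shJmjd3, against 430.5 ± 38.9 (SD, n = 2) with shLuc and 458 ± 37.5 with FLAG. Epcam was at 194 ± 1.41 against 674 ± 5.66 and 576 ± 41.7. The growth factor gene Fgf4 of pluripotent cells was at 60.5 ± 4.95 against 206 ± 43.1 and 144 ± 2.12, and the interferon-induced membrane protein Bst2 at 279 ± 32.5 against 931 ± 69.3 and 422 ± 48.1. Col3a1 was again at 59744 in both shJmjd3 libraries, against 17625 ± 3257 with shLuc and 27861 in both libraries with FLAG.

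Of the 14715 genes, limma called 5983 at day 8, 3155 higher and 2828 lower, with 344 and 678 past 2-fold. Against FLAG 4811 were called, 2723 of them in the same direction as against shLuc. No epithelial gene rose and 20 of 25 fell (21 adjusted over the list alone), at a median log2 change of -1.59 (camera adjusted p = 4.1e-09, adjusted p = 0.012 with an estimated correlation). Against FLAG 18 fell (camera adjusted p = 3.8e-11, adjusted p = 0.0034 with an estimated correlation). The interferon list fell in 18 of 22 genes (18 adjusted over the list alone, camera adjusted p = 1.5e-07, adjusted p = 0.028 with an estimated correlation) and in 13 against FLAG (camera adjusted p = 0.00029, adjusted p = 0.067 with an estimated correlation), with Ddx58 at -1.17 against shLuc and -0.47 against FLAG. Pluripotency genes fell in 11 and rose in 2 of 24 cases (12 and 2 adjusted over the list alone, camera adjusted p = 0.0030, adjusted p = 0.15 with an estimated correlation), and in 13 cases against FLAG (camera adjusted p = 4.3e-06, adjusted p = 0.022 with an estimated correlation). Nanog was at 62 and 78 with shJmjd3 and 76 and 62 with shLuc, a log2 difference of 0.02, and at -1.59 against FLAG (limma adjusted p = 0.030), so whether it was lower depends on the control. Mesenchymal genes rose in 12 and fell in 7 of 30 cases against shLuc (camera adjusted p = 0.36) and rose in 13 and fell in 2 against FLAG (camera adjusted p = 0.00084, adjusted p = 0.022 with an estimated correlation). The stratified epithelium list fell in 10 and rose in 3 of 18 cases (camera adjusted p = 0.0019, adjusted p = 0.16 with an estimated correlation), with Krt6a at -2.45 (SE 0.15) against shLuc and -1.85 against FLAG, where 9 members fell and 0 rose (camera adjusted p = 0.00029, adjusted p = 0.088 with an estimated correlation).

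Cell cycle genes rose in 23 and fell in 1 of 28 cases at day 8 (24 and 1 adjusted over the list alone, camera adjusted p = 1.5e-07, adjusted p = 0.20 with an estimated correlation), with the mitotic kinase Aurka at 0.66 (SE 0.05) and the replication factor Mcm2 at 0.44 (SE 0.05). Against FLAG 14 rose and 0 fell (camera adjusted p = 0.00017, adjusted p = 0.36 with an estimated correlation). Ink4 and p53 targets fell in 11 and rose in 4 of 21 cases against shLuc (camera adjusted p = 0.036, adjusted p = 0.20 with an estimated correlation), with the list going the other way against FLAG (camera adjusted p = 0.163). Cdkn2a fell against both, at -0.93 and -0.50, while Cdkn2b was at -0.73 against shLuc and -0.28 against FLAG (limma adjusted p = 0.10). Phf20 was at 0.23 (limma adjusted p = 0.072) and Nipbl at -0.06 (limma adjusted p = 0.57) against shLuc. Dissociation and stress genes fell in 9 and rose in 2 of 18 cases against shLuc (camera adjusted p = 0.017, adjusted p = 0.11 with an estimated correlation), but fell in 8 and rose in 4 against FLAG (camera adjusted p = 0.31). The smooth muscle myosin Myh11, at -5.20, was among the largest falls against shLuc, where it was listed at 327 and 265, against 12 and 4 with shJmjd3 and 22 and 20 with FLAG. Among the largest rises, the neural adhesion molecule Ncam2 was listed at 0 in both shLuc libraries, 247 and 308 with shJmjd3 and 124 and 136 with FLAG.

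**Figure D2:**
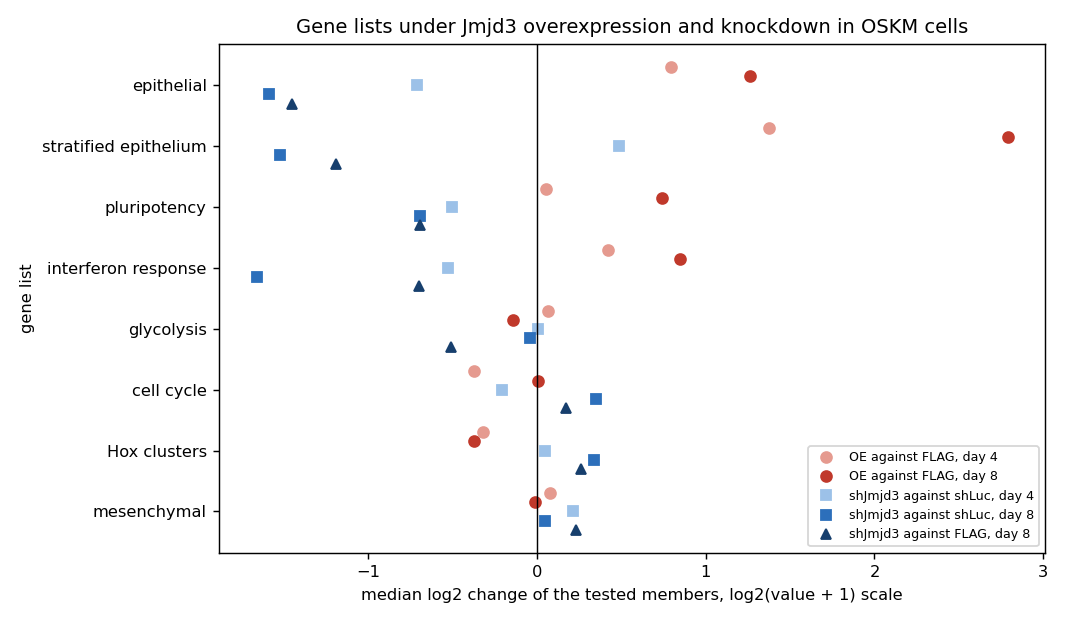
Median log2 change, on the log2(value + 1) scale, of the tested members of 8 gene lists in 5 comparisons of OSKM libraries; circles are overexpression against FLAG, squares shJmjd3 against shLuc and triangles shJmjd3 against FLAG at day 8. The epithelial median was 1.26 with overexpression and -1.59 with knockdown at day 8, and the cell cycle median -0.37 with overexpression at day 4.

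Overexpression and knockdown had separate control libraries, so their calls could be set against each other. Genes are not independent replicates in these counts, and both comparisons share each gene's estimate of spread. That can raise the sharing in every direction, so the Fisher p-values below do not measure the evidence exactly. At day 8, 1722 genes were called in both and 1073 of them (62.3%) went in opposite directions. Genes higher with overexpression and lower with knockdown numbered 604, where 280.4 would be shared by independent lists, with a Fisher exact p of 1.1e-95. The reverse pair numbered 469 against 325 for independent lists (Fisher exact p = 4.5e-20). Lower in both were 349 against 291 (Fisher exact p = 8.6e-05), and higher in both 300 against 312.8 (Fisher exact p = 0.40). Cdh1, Epcam, Sfn, Krt6a, Ddx58 and Cdkn2a were among the genes higher with overexpression and lower with knockdown. At day 4, 1167 genes were called in both and 522 (44.7%) were opposite, with 375 higher with overexpression and lower with knockdown, against 197.2 for independent lists (Fisher exact p = 8.4e-42), and 147 the reverse, against 168.7 (Fisher exact p = 0.058). Shared directions also exceeded independent lists at day 4, with 362 lower in both against 176 (Fisher exact p = 1.4e-49) and 283 higher in both against 189.1 (Fisher exact p = 7.0e-14). Overexpression at day 4 and at day 8 shared 745 called genes, 624 in the same direction, and knockdown at the 2 days shared 3510, 3159 in the same direction.

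Control cells at day 8 were compared with those at day 4 to show how gene expression changed as reprogramming advanced. Every tested epithelial gene was higher at day 8, all 25 of them called, at a median log2 change of 3.46. Epcam rose from 24.5 ± 2.12 (SD, n = 2) to 576 ± 41.7 (SD, n = 2) with FLAG and from 37 ± 7.07 to 674 ± 5.66 with shLuc. Every one of the 18 glycolysis genes rose as well, with the glucose transporter gene Slc2a1 at 3.55 (SE 0.03) and the pyruvate dehydrogenase kinase gene Pdk1 at 2.88 (SE 0.04). Nanog rose by 3.61 (SE 0.35) and the RNA-binding protein gene L1td1 of pluripotent cells by 3.17 (SE 0.04), while smooth muscle actin (Acta2) was at -2.33 (SE 0.03) and Cdh2 at -1.76 (SE 0.05).

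limma called 8989 genes between the days, 4157 higher and 4832 lower at day 8, with 1007 and 927 past 2-fold. The epithelial list had a camera adjusted p of 3.7e-13 and an adjusted p = 0.0019 with an estimated correlation, and the glycolysis list 3.7e-13 and an adjusted p = 0.0010 with an estimated correlation. Pluripotency genes rose in 17 and fell in 4 of 24 cases (camera adjusted p = 7.1e-05, adjusted p = 0.029 with an estimated correlation). Stratified epithelium rose in 15 and fell in 1 of 18 cases (camera adjusted p = 3.0e-06, adjusted p = 0.029 with an estimated correlation) and interferon response rose in 18 and fell in 1 of 22 (camera adjusted p = 5.3e-05, adjusted p = 0.029 with an estimated correlation). Mesenchymal genes fell in 20 and rose in 4 of 30 cases (camera adjusted p = 0.00023, adjusted p = 0.013 with an estimated correlation), and Hox genes fell in 19 and rose in 1 of 28 (camera adjusted p = 0.0012, adjusted p = 0.029 with an estimated correlation). Bivalent developmental regulators fell in 11 and rose in 2 of 17 cases, with Hand2 at -2.03 (camera adjusted p = 0.034, adjusted p = 0.094 with an estimated correlation). Ink4 and p53 targets fell in 13 and rose in 4 of 21 cases (camera adjusted p = 0.046, adjusted p = 0.16 with an estimated correlation). Among them Cdkn2a rose by 1.28 (SE 0.09) and Cdkn2b fell, at -0.50 (SE 0.09), while Phf20 was at 0.26 (SE 0.06) and Nipbl at 0.17 (SE 0.05). The largest rise was that of Ndufa4l2, a mitochondrial protein induced by low oxygen, at 1440 and 1480 with FLAG at day 8 against 0 and 1 at day 4, and among the largest falls was Ncam2, at 370 and 402 and 185 and 405 in the FLAG and shLuc libraries of day 4, 124 and 136 with FLAG at day 8 and 0 in both shLuc libraries of day 8. Pou5f1 was at 27802 in every day 8 OSKM library with its own value, so changes at this level could not be resolved.

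The effect of overexpression differed between the days for 1353 genes by limma's interaction test. Among pluripotency genes the difference was positive in 7 and negative in 1 of 24 (camera adjusted p = 0.0043, adjusted p = 0.16 with an estimated correlation), with Tdgf1 at a log2 difference of effects of 3.18 (SE 0.55), Tet1 at 1.11 (SE 0.18) and Dppa5a, a marker of naive pluripotent cells, at 5.09 (SE 1.33). Esrrb, a transcription factor of the same cells, was at 5 and 3 with FLAG and 146 and 126 with overexpression at day 8, and at 0 and 0 and 0 and 0 at day 4. Cell cycle genes had a positive difference in 21 of 28 (camera adjusted p = 1.9e-19, adjusted p = 0.091 with an estimated correlation), with Ccna2 at 0.57 (SE 0.06). The effect of knockdown differed for 2787 genes, with Krt6a at -4.58 (SE 0.21) and Sfn at -2.54 (SE 0.16) lower at day 8 relative to day 4, and the replication factor Mcm7 higher, at 0.80 (SE 0.08). With FLAG instead of shLuc as the control, 892 of these 2787 kept call and direction and 100 were called the other way. Krt6a was higher than with shLuc at day 4, at 2.12, and lower at day 8, at -2.45. Stratified epithelium had 7 of 18 members lower (camera adjusted p = 9.1e-05, adjusted p = 0.065 with an estimated correlation) and the cell cycle list 25 of 28 higher (camera adjusted p = 1.1e-17, adjusted p = 0.058 with an estimated correlation). Without overexpression replicate 1 of day 8 the first count was 869, and without FLAG replicate 1 of day 4 it was 888.

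The shUtx libraries were described by the authors' deposited table of group means, which has no spread and so no test. Kdm6a was at 276 with shUtx and 703 with shLuc at day 4, and at 364 and 778 at day 8. Kdm6b was at 1486 and 1516 with shUtx, against 1356 and 1232 with shLuc. In these means Cdh1 was at 260 with shUtx at day 8, 438 with shLuc, 468 with FLAG and 206 with shJmjd3. The median log2 ratio of the 26 epithelial genes was -0.78 against shLuc and -0.81 against FLAG at day 8, with 12 of them 2-fold or more lower against shLuc and 0 higher. Both medians lay below those of all 10000 random lists of the same size and mean value. Such lists carry neither the correlation between list members nor the spread between libraries, so these positions are descriptive. At day 4 the median was -0.64 against shLuc but -0.12 against FLAG, at percentile 10.2 of the random lists. Mesenchymal genes had medians of 0.47 and 0.59 against shLuc and FLAG at day 8, but 0.01 and 0.01 at day 4. The interferon median was -0.80 against shLuc but -0.08 against FLAG at day 8, and -0.71 and 0.04 at day 4. Over 11885 genes, 348 were 2-fold higher and 437 lower than shLuc at day 8, and 224 and 298 at day 4. Among the largest ratios at day 8, Akr1c18, a steroid-metabolising enzyme, was at 10030 with shUtx against 702.5 with shLuc and 545 with FLAG, and the mitochondrial peroxidase Prdx3 at 62.5 against 788.5 and 723.5. The log2 ratios of the hairpins against Utx and Jmjd3, which share the shLuc means, correlated across genes at r = 0.552 at day 8, where unchanged groups simulated against the same control gave 0.495. Their covariance was 0.175 against a simulated 0.0338, and with separate controls r was 0.169 or -0.00345 by which control went with which hairpin. At day 4 r was 0.467 against a simulated 0.500, the covariance 0.111 against 0.0342, and r with separate controls 0.0912 or -0.100. Genes are not independent replicates in these correlations.

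In MEFs without reprogramming factors, knockout cells were compared with wild-type cells over both passages. limma called 1 of 14449 genes, and 116 had an unadjusted p under 0.05. That gene, Zfp985, a zinc finger gene of a family with near-identical copies, was listed at 0 in both wild-type libraries and at 224 and 240 in the knockout libraries at passages 2 and 4. Of the other genes with the smallest p, the organic anion transporter gene Slco4c1 was at 4 and 5 in knockout and 230 and 201 in wild-type MEFs (limma adjusted p = 0.31). The receptors Olfr1440 and Vmn1r29, whose families hold near-identical copies, had adjusted p of 0.098 and 0.37 by limma, and the unnamed Gm43751 0.37. The count was 5 without the knockout library of passage 2, 0 without that of passage 4 and 4 without the wild-type library of passage 2. Cell cycle genes were the only list to pass, with a camera adjusted p of 0.027 at a median log2 difference of 0.10, 0 members higher adjusted over the list alone and an adjusted p = 0.99 with an estimated correlation. Cdkn2a was at 510 at passage 2 and 1348 at passage 4 in knockout MEFs, and at 354 and 1711 in wild-type MEFs. The gene-by-gene differences at passage 2 and at passage 4 correlated at r = -0.0217 across genes. In simulated data, 47% of 2-fold changes were recovered in the overexpression comparison of the same design.

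Jmjd3 overexpression in MEFs was compared with the FLAG vector, with 1 library at each passage. The mitotic kinase gene Plk1 was at 82 at passage 2 and 62 at passage 4, against 322 and 174. Desmoplakin (Dsp), a component of epithelial junctions, was at 2060 and 682, against 116 and 220, and Perp, a junction protein and p53 target, at 3120 and 767, against 204 and 146. Cdkn2a was at 4859 and 2566, against 741 and 1916.

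None of these genes passed over all 14449 genes, where limma called 2, and 1525 had an unadjusted p under 0.05. The called genes were Klhl1, listed at 0 in both FLAG libraries and at 175 and 130 with overexpression, and AC122355.1, at 1 in both overexpression libraries and 184 and 302 with FLAG. Klhl1 was also at 303 and 245 in wild-type MEFs. Anxa8, which encodes an annexin of epithelial cells, was at 4034 and 1350 against 656 and 337 (limma adjusted p = 0.19), and Plk1 and Olfr1440 had adjusted p of 0.14 and 0.090 by limma. The count was 6 without the FLAG library of passage 4, 3 without that of passage 2 and 0 without either overexpressing library, and 1433 in a fit that also held the OSKM libraries. Adjusted over the list alone, 23 of 28 cell cycle genes fell (camera adjusted p = 9.2e-23, adjusted p = 0.47 with an estimated correlation), 5 of 9 epithelial genes rose (camera adjusted p = 6.1e-05, adjusted p = 0.47 with an estimated correlation) and 2 of 21 Ink4 and p53 targets rose (camera adjusted p = 5.6e-06, adjusted p = 0.62 with an estimated correlation), against 0, 0 and 0 over all genes. Interferon response genes were lower than with FLAG at a median of -0.91, with 0 called (camera adjusted p = 3.7e-06, adjusted p = 0.62 with an estimated correlation). The effects at the 2 passages correlated at r = 0.0901 across genes.

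**Figure D3:**
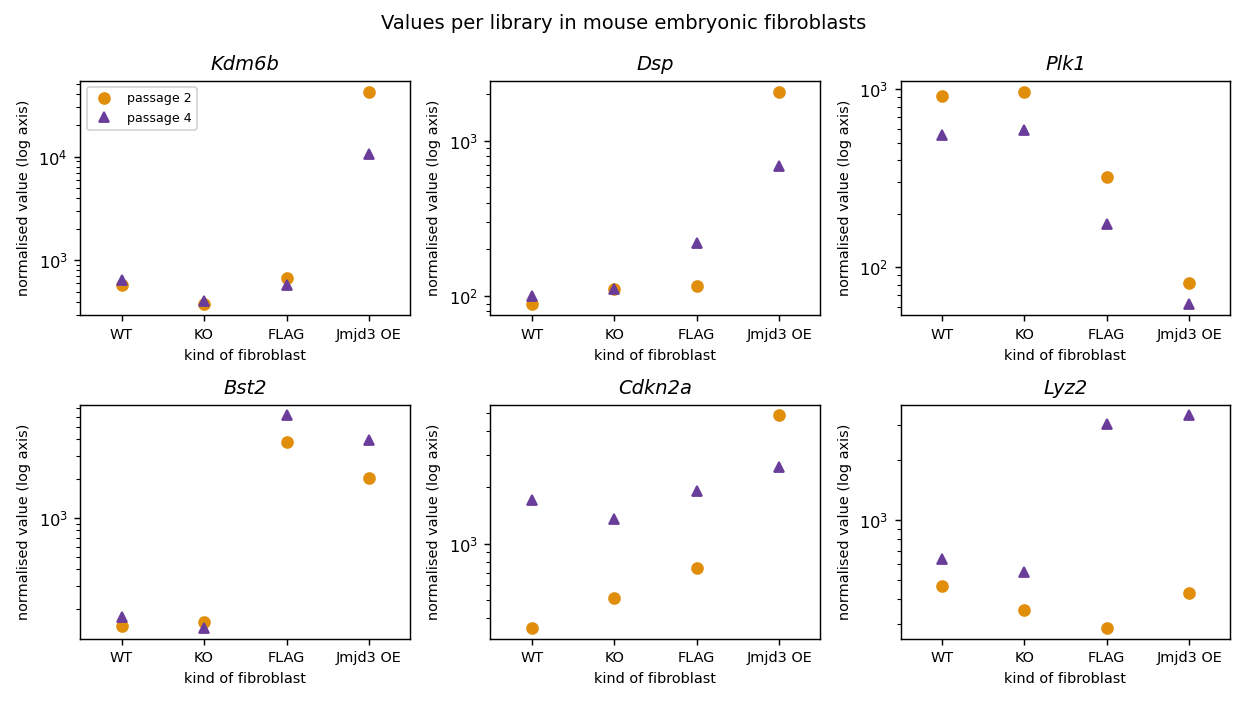
Normalised values of 6 genes in the 8 MEF libraries on a log axis, by kind of MEF; circles are passage 2 and triangles passage 4, each a single library. Dsp was at 2060 and 682 with Jmjd3 overexpression, Bst2 at 3806 and 6132 with FLAG against 146 and 172 in wild-type MEFs, and Lyz2 was higher at passage 4 in infected cells, at 3041 and 3364.

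The FLAG vector was compared with uninfected wild-type MEFs as the background that overexpression carries. Interferon response genes were far higher in infected cells. The transcription factor Irf7 was at 1274 and 2818 at passages 2 and 4, against 30 and 26 in wild-type cells, and Bst2 at 3806 and 6132, against 146 and 172. The chemokine gene Ccl7 rose from 196 and 274 to 1170 and 2756. Cartilage collagen Col2a1 fell from 7130 and 2137 to 303 and 94.

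limma called 612 genes, 333 higher and 279 lower, 224 and 149 of them past 2-fold. The interferon list rose in 21 of 26 genes (26 adjusted over the list alone) at a median log2 change of 4.65, with a camera adjusted p of 4.2e-25 and an adjusted p = 0.42 with an estimated correlation. Cell cycle genes fell in 4 of 28 cases (17 adjusted over the list alone, camera adjusted p = 5.8e-11, adjusted p = 0.57 with an estimated correlation). Mesenchymal genes rose in 3 of 30 cases (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.048, adjusted p = 0.42 with an estimated correlation), with the surface glycoprotein Thy1 at 7586 and 10046 against 2562 and 3718. Eno1b, a near-identical copy of an enolase gene and so of uncertain value, had the largest rise, at 4180 and 3808 with FLAG and 0 in both wild-type libraries. The count was 82 without the FLAG library of passage 2, 14 without that of passage 4, 29 without the wild-type library of passage 2 and 22 without that of passage 4, and 174 without a passage term.

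Passage 4 was compared with passage 2 over the 4 kinds of MEF. Among the largest falls with passage were the growth factor gene midkine (Mdk), from 698 to 42 in wild-type and 317 to 42 in FLAG cells, and the Wnt modulator Sfrp2, from 400 to 12 and 108 to 24. The interferon-induced GTPase Irgm1 rose, from 431 to 1281 and 3913 to 9341. limma called 255 genes, 86 higher and 169 lower at passage 4. Cell cycle genes fell in 1 case over all genes and 16 of 28 adjusted over the list alone (camera adjusted p = 8.3e-08, adjusted p = 0.81 with an estimated correlation), and Hox genes rose in 3 cases and 10 of 30 adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.81 with an estimated correlation). Macrophage markers had 0 of 14 members called (camera adjusted p = 0.0010, adjusted p = 0.81 with an estimated correlation). Lysozyme 2 (Lyz2) was at 3041 and 3364 at passage 4 in infected cells, against 286 and 429 at passage 2. Cdkn2a was not called, at 1.03 (SE 0.52). Without either library of FLAG, knockout or wild-type cells no gene was called, and without either overexpressing library 3 were.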

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

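Chosen only after the results were seen were the tests of equal replicate values, of the shLuc libraries as the source of the knockdown and epithelial differences, of the loss of Jmjd3 at both days, of shared receptor reads and of genetic background, and the intervals used to read the 2 shares of MEF genes and the shares of opposite directions.

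Effects that differed between day 4 and day 8 were singled out by limma's interaction test. For overexpression these were 1353 genes, of which 805 had the larger effect at day 8 and 121 were called in opposite directions at the 2 days. The median difference, day 8 minus day 4, was 0.50 for pluripotency genes, 0.39 for cell cycle genes, 1.42 for stratified epithelium, 0.11 for cohesin and elongation genes and -0.13 for glycolysis. These 5 lists passed camera, but none passed with an estimated correlation, where the adjusted p was 0.085 for glycolysis to 0.21 for cohesin and elongation genes. Keratin genes went both ways, with Krt6a at 0.79 and Krt8 at -1.33. Glycolytic genes also split, with the glucose transporter gene Slc2a3 at 0.66, the aldolase gene Aldoa at -0.52 and Pdk1 at -0.45. Others were Ddx58 at 0.62, Igfbp3, which encodes a binding protein of insulin-like growth factors, at 0.45, Klf4 at -0.46 and the neurofilament gene Nefl at -0.86.

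For knockdown against shLuc 2787 genes differed between the days, 1530 of them with the larger effect at day 8 and 351 called in opposite directions. With FLAG as control 892 of the 2787 kept call and direction and 100 were called the other way, so most of this count depends on the control. Median differences were -0.80 for epithelial genes, -1.41 for stratified epithelium, -1.13 for interferon response, -0.49 for the secretory phenotype, -0.28 for Ink4 and p53 targets, -0.24 for dissociation and stress, -0.078 for glycolysis, 0.15 for H3K27 machinery and 0.56 for cell cycle. With an estimated correlation none of these lists passed, with adjusted p from 0.058 for the epithelial, interferon, cell cycle and stress lists to 0.20 for H3K27 machinery. Among keratin genes Krt6a was at -4.58, Krt16 at -3.99 and Krt14 at -1.28, while Krt8 was at 0.72. Epcam was at -1.08, Epha2, an ephrin receptor gene, at -1.68, Cdkn2b at -0.75, Junb at -0.52 and Lamb1 at -0.33. Positive differences were those of Ccnb2 at 0.87, Pou5f1 and Meox2 at 0.71 each, Col3a1 at 0.56, Klf4 at 0.54, Nefl at 0.48, Fbn1 at 0.33 and Suz12 at 0.29. Col3a1 stood at the highest value of the table with shJmjd3 at both days, so its difference is that of shLuc between the days. Pou5f1 had 1 shared value in shJmjd3 and shLuc at day 8, so its difference rests on day 4.

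The first pattern weighed was the number of genes that differed between shJmjd3 and shLuc, 5661 at day 4 and 5983 at day 8. Equal replicate values are argued against as the whole source, since of the 10675 genes without such values in any of the 8 groups, fitted alone, 39.5% were called at day 4 and 41.3% at day 8, against 38.5% and 40.7% of all genes. Replicates that differ by only a small step were not tested. Loss of Jmjd3 has the value it needs at day 8, where 62.3% of the genes also called with overexpression, which has other controls, went in opposite directions. But the controls themselves differed in 5153 genes at day 8, and genes high with both overexpression and shLuc would also give opposite calls. At day 4 the share was 44.7%, under the 45% bound set against it, with 522 genes opposite and 645 in the same direction. Its exact 95% interval, 41.9% to 47.6%, reaches past that bound. Only by this interval, chosen after the value was seen, is loss of Jmjd3 left open there. An odd shLuc control could still contribute, since FLAG was nearer to shJmjd3 than to shLuc for 51.1% of the called genes at day 4 and 51.8% at day 8, near the 50.3% and 51.2% over all genes, so the 2 sources cannot be told apart for the count. For the 20 epithelial genes called lower at day 8 it is argued against, as their median against FLAG was -1.46, with 20 of 20 below FLAG and 15 called. These 20 were chosen with the same shJmjd3 libraries, which can lower their difference from FLAG. The whole epithelial list, not chosen in this way, was also lower than FLAG by camera, at the fixed and at the estimated correlation.

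The next pattern was 215 genes called with changes of 8-fold or more under overexpression or knockdown, 133 of which were listed at 0 in some OSKM library. Reads shared between near-identical receptor genes do not account for most of the set, since 11.6% of it were olfactory or vomeronasal receptors. Such receptors were 326 of the 14715 genes tested, a smaller share than in the set. Transcript GC content in the authors' normalization may contribute, because 40.2% of these genes (86 of 214 with a value) lay among the 10% of tested genes with the lowest GC content. A response to the Jmjd3 level also has the values it needs, as 47 of 55 (85.5%) that were called in both overexpression and knockdown on a day went in opposite directions. Both remain open, and genes of low GC content also had lower values, with a median of 107.5 in that class against 285.9 in the next. GC content also went with the calls for overexpression at day 8 as a whole. Of the lowest 10% of genes 75 of 1471 were called, and of the highest 10% 412 of 1470. The next lowest class, at a median value of 285.9 against 275.8 in the highest, had 201 of 1470 called.

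The last pattern was 5 genes listed at 0 in the 4 wild-type and knockout MEF libraries and at 100 or more in the 4 FLAG and overexpression MEF libraries, with 0 genes the other way round. They were Gm21411, Zfp988, Ifi202b, Fnd3c2 and Gm47034, named after their values were seen. An interferon response to infection cannot be told apart, since 1 of the 5 (20%, exact 95% interval 0.505% to 71.6%) was an interferon-type gene, Ifi202b, a share that met the bound set in advance against it but with too few genes to decide. Another genetic background of the wild-type and knockout MEFs cannot be told apart either, since 0% of the other 4 genes (upper limit 60.2%) were at 50 or more in all OSKM and iPSC libraries, and a value of 0 can be a failed estimate. Ifi202b itself was at 554 to 767 in all 16 OSKM libraries and 667 in the iPSC library, where the median of the interferon list was 9 to 60.

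Chance as the source of the difference between days was weighed by splits of libraries. With the kind of control in the fit of the 8 control libraries alone, the real split gave 7595 genes and was the only 1 of 34 splits to give as many, and the highest other gave 2. This argues against a chance split of these libraries. Splits that mix the days leave the day effect in the spread, which lowers their counts. Replicates may be technical, so differences between cultures are not excluded. The split of FLAG against shLuc could not be fitted. For passage in MEFs, 3 of the 32 splits that could be fitted gave as many genes as the real 255, so by this count chance could not be excluded, and 3 more could not be fitted. The other 2 gave 1086 each. They put both FLAG libraries on 1 side and both overexpressing libraries on the other, so with the kind in the fit they contrast the passages of knockout and wild-type cells. Among the 8 splits with 1 library of each kind on each side, the highest other than the real one gave 2.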

How the results depend on the processing

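FLAG as the control of the knockdown, leaving out tied genes and leaving out genes at 0 were alternatives chosen after seeing the data.

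Counts of called genes under every planned setting except those named here stayed within 1.5 times the reported count. Without a filter, 2 genes were called for the MEF knockout and 8 for MEF overexpression. With the libraries of the groups compared only, 332 genes were called for overexpression at day 4 and 1446 at day 8, from fits with 2 residual degrees of freedom. Without a passage term the knockout gave 2 and FLAG infection 174. A fit over 24 libraries gave 21 for the knockout, 1433 for MEF overexpression, 3549 for FLAG infection and 4361 for passage, with 2156 of these higher at passage 4, where the spread between OSKM replicates enters the test. In the other deposited MEF table overexpression gave 1, and without genes at 0 the knockout gave 0 and overexpression 1. FLAG as control gave 3724 genes in the knockdown at day 4.

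Leaving out 1 library, with its lone partner assumed to vary like the other groups, gave 961 to 1511 genes for overexpression at day 4, 1495 to 2192 at day 8, 869 to 1045 for the difference of its effect between days, 0 to 5 for the knockout, 0 to 6 for MEF overexpression, 14 to 82 for FLAG infection and 0 to 3 for passage. The knockdown gave 4296 to 4520 at day 4 and 4665 to 4943 at day 8. No pseudocount of 10, robust fit or mean of at least 50 moved a count of OSKM calls past 1.5 times. Quantile normalization and the median shift did not either, but they could hardly do so. The values already had nearly equal medians and totals in every library, and the median shift left every count unchanged.

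With the replicate block, overexpression gave 1863 genes at day 4 and 2870 at day 8, and the knockdown 5616 and 5973. Deviations of libraries with the same number correlated between -0.0695 and 0.0628 over 28 pairs of groups, so the numbers do not pair the samples.

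Every reversal came with FLAG as control, and the cause was not tested. In the knockdown at day 4 the log2 change was 0.15 for Bst2, 0.17 for Col4a1, -0.024 for Epha2, -0.21 for Fabp7, 0.010 for Klf4, -0.085 for Lamb1, -0.075 for Map2, 0.13 for Meox2, 0.032 for Myc, -0.62 for Prl3d3, 0.66 for Rsad2 and -0.12 for Trp53inp1. At day 8 it was 0.54 for Acta2, -0.10 for Ccnb2, -0.51 for Dab2, 0.062 for Ei24, -1.59 for Nanog, 0.31 for Stmn2, 0.30 for Tagln, 0.12 for Tbx20 and 0.22 for Trim26. For the difference between days it was 0.54 for Acta2, 0.057 for Cdkn1a, -0.086 for Cited1, -0.54 for Dab2, -0.0073 for Ezh2, -0.39 for Insm1, -0.35 for Kdm6b, -0.19 for L1td1, 0.038 for Lamb1, -0.10 for Mmp2, -0.0086 for Rad21, 0.055 for S100a4, -2.34 for Tmprss15 and 0.10 for Tubb3. Camera's adjusted p of the lists that changed direction was 0.403 for interferon response at day 4, 0.163 for Ink4 and p53 targets at day 8, and 0.844 and 0.935 for Ink4 and p53 targets and the H3K27 methylation machinery in the difference between days.

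Over all alternatives, 616 calls of named genes, counted in each comparison, kept direction and call in 8272 cases, lost the call in 1043 and reversed in 33. List results were kept in 2002 cases, lost in 114, gained in 64 and reversed in 4. Of 209 list results 81 passed camera, and 59 of these 81 lost their call with an estimated correlation. Tests for raw counts were not run, since the values are normalised scores. Depth cannot be read from these values, so its limit on genes of low value was not examined.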

Other observations

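The test of whether overexpression advances cells along the change from day 4 to day 8 was chosen after the results were seen, as was FLAG as the control of the shJmjd3 and shLuc libraries.

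The shLuc and FLAG controls differed in several groups of genes at day 8. Glycolysis genes were lower with shLuc than with FLAG in 13 of 18 cases (limma camera adjusted p = 2.2e-08, adjusted p = 0.0047 with an estimated correlation), among them Aldoa at -0.84, Pdk1 at -0.64 and Slc2a1 at -0.47. They were lower with shJmjd3 than with FLAG as well, in 16 cases (camera adjusted p = 8.4e-15, adjusted p = 0.00062 with an estimated correlation), with Slc2a1 at -1.20 and the phosphofructokinase gene Pfkp at -0.78. Ink4 and p53 targets were higher with shLuc than with FLAG in 16 cases and lower in 2 of 21 (camera adjusted p = 5.6e-05, adjusted p = 0.060 with an estimated correlation). Interferon response genes were higher in 8 of 22 cases (camera adjusted p = 0.00039, adjusted p = 0.11 with an estimated correlation), and in 9 at day 4. Skeletal actin (Acta1) was at 3.47 and Myh11 at 3.75, while the muscle list had 2 of 5 members called and did not pass (camera adjusted p = 0.17). Nanog was at 76 and 62 with shLuc and 212 in both FLAG libraries, a log2 difference of -1.61 (limma adjusted p = 0.026), and Tet1 at -1.48.

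The iPSC library stood far from the OSKM cells in genes of the pluripotent state. It held Nanog at 9344, Esrrb at 5280, Zfp42 at 2948, Dppa5a at 12357, Tdgf1 at 5092, Utf1 at 687 and Tet1 at 5702. Overexpressing cells of day 8 held Nanog at 382 and 395, Esrrb at 146 and 126, Dppa5a at 166 and 82 and Utf1 at 56 and 46. Zfp42 and Utf1 were chosen after their values were seen. Cdh1 was at 3624 and Epcam at 480 in the iPSC library, so Epcam was lower there than in the FLAG cells of day 8. Krt17 was at 38, against 611 and 642 with FLAG and 3009 and 2474 with overexpression at day 8. The surface marker gene Thy1 was at 808, Cdkn2a at 227 and Klf4 at 2326. Pou5f1 was at 13209, below the 27802 of the OSKM libraries of day 8. OSKM cells carried Pou5f1 and Klf4 on vectors as well, so these values do not compare the cells' own genes. The iPSC values come from 1 library of another factor mix, so no difference was tested.

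The interferon list separates infected from uninfected MEFs. Its median value over genes was 1791.5 in FLAG and 1027 in overexpressing MEFs, and 51 in wild-type and 57.25 in knockout MEFs. Both FLAG and overexpressing cells are labelled as infected, so the lower level under overexpression is a difference between infected cultures. No member of the list was called for it over all genes tested in limma.

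Macrophage markers were read in the MEF libraries because camera placed their list higher at passage 4. Besides Lyz2, the complement gene C1qa was at 32 and 530 with FLAG at passages 2 and 4, 28 and 416 with overexpression, 28 and 56 in knockout and 58 and 54 in wild-type cells. Cd68, a lysosomal protein of macrophages that fibroblasts also express, was at 50 and 271 with FLAG and 64 and 87 in wild-type cells.

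Pluripotency, epithelial and glycolysis genes rose from day 4 to day 8, and the first 2 of these lists also rose under Jmjd3 overexpression at day 8. Glycolysis genes instead fell in 10 and rose in 1 of 18 cases there (camera adjusted p = 0.0041, adjusted p = 0.034 with an estimated correlation), against what an advance would give unless these genes fall again after day 8. But the list was also lower than FLAG at day 8 with shLuc and shJmjd3, and at a median of -0.38 in the shUtx means. High values in the FLAG libraries can therefore not be told apart from an effect of overexpression on these genes. If overexpression moved cells faster along the same course, its changes at day 4 would correlate with those from day 4 to day 8 in the shLuc libraries, which share no library with that comparison. The correlation across genes was 0.0783, but overexpression at day 4 and at day 8 correlated with each other at only 0.139, so a low value does not count against an advance, which cannot be told apart from other effects of overexpression by this test. Of the 1263 genes called in both comparisons 556 went in opposite directions. All 4 pairs of directions exceeded independent lists, with 447 against 213.7 higher in both, 260 against 217.1 lower in both, 277 against 190.7 higher at day 8 and lower with overexpression, and 279 against 243.2 the reverse. For overexpression at day 8 the correlation was 0.121, and 930 of 1867 went in opposite directions. Excesses were of similar size in all 4 pairs, at 441 against 310.5, 496 against 366.8, 450 against 322.2 and 480 against 353.5, so the day 8 counts do not favour an advance. At day 4 the largest excess was that of genes higher in both. Genes are not independent replicates in these counts.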
